A study of Rattus norvegicus with 8 samples.

How the data were processed

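Gene expression was measured by RNA sequencing of heart tissue from Sprague Dawley rats aged 3 months. The labels put 4 libraries in normoxia and 4 in chronic hypoxia, and their extraction protocol describes 4 hypoxic and 4 normoxic rats, so each library was taken as 1 animal. The oxygen level, the length of exposure, the sex of the animals and the part of the heart sampled are not given in the sources used here. Total RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols.

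The authors deposited a table of read counts per gene for each library, with whole-number values that were not normalized. They also deposited a table of FPKM values (counts scaled by gene-model length and library total) for each library. Bowtie2 2.2.3, HISAT2 2.1.0, HTSeq 0.6.0, bcl2fastq and the rat genome build rn6 are named per the submitters' processing notes. Which aligner made these counts, the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads of near-identical gene copies, of overlapping genes and of antisense partners therefore cannot be separated in these values.

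Each table listed the same 21549 Ensembl gene IDs, and no line was a summary line. Dividing count by FPKM and by the library total returned 1 whole length per gene, within a relative tolerance of 0.001, in 100% of the values above 0, and the largest distance from the whole length was 0.00469 bp. These lengths, with a median of 1897 bp, were used as gene-model lengths. Of them, 44.1% were multiples of 3, against 33.3% by chance, so they were not treated as coding lengths. The deposited FPKM values thus hold the counts scaled by library total and length, with no other normalization.

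The files do not pair the gene IDs with names. The gene table used here (assembly GRCr8) matched 0 of the 21549 IDs, so no gene symbol or genome position is given. The 40 gene lists and the anchor genes that were fixed in advance could not be tested, nor could shares of mitochondrial or red blood cell transcripts. The rule for naming genes took the 10 largest changes in each direction among genes with an adjusted p under 0.05, a mean of at least 1 CPM (counts relative to the scaled library size), a gene symbol and groups that did not overlap, plus the anchors and list members. Without symbols it names no gene. The 2 largest changes in each direction that met its other conditions are printed by ID.

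The comparison of chronic hypoxia with normoxia was fitted to the counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM (trimmed mean of M values), and the quasi-likelihood test was used with group as the only term. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are described as called. The SE of a log2 fold change was computed from the test statistic. Log2 CPM used a prior count of 2. Measures with 1 value per library were compared by two-sided exact permutation tests over the 70 assignments of 8 libraries to 4 and 4, for which the smallest possible exact p is 0.0286, with Benjamini-Hochberg adjustment over 10 measures. Most of these measures were chosen after the data were seen, and several are related. An adjusted p under 0.05 is reached only because several of them share the smallest possible p. These used scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

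The main tests, the rule for named genes, the gene lists and most alternatives were chosen before the data were examined. The alternatives were other scalings (RLE, upper quartile, library totals alone), DESeq2 1.42.0, limma-voom (limma 3.58.1), robust dispersions, other filters, the replicate number as a block, each library left out, counts thinned to the smallest total with random seed 20240501, the 20 most abundant genes left out, and limma with a trend on log2(FPKM + 1) or log2(FPKM + 0.1). A correction for gene-model length, voom with 1 variance per group and the removal of hypoxia libraries 1 and 2 or 3 and 4 were chosen after seeing the data. So were the correlations of fold changes with length, apart from that over the called genes, and the per-library measures other than total counts and the share of the 10 most abundant genes. The length correction subtracted a lowess curve (span 0.3) of log2 CPM on log2 length from each library through offsets. The curve was fitted over all abundances together, so it can leave part of a trend that differs with abundance.

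Library totals ran from 26229304 to 32160710 counts, and 14214 genes holding 99.9% of all counts were tested. The remaining 7335 were too low for the filter. A count of 0 allows up to 3 counts, which is between 0.0895 and 0.115 CPM depending on the library. Such limits cover counting error only. The edgeR script was tested on simulated data for this comparison, in 5 draws of all 14214 genes with 200 genes changed per draw. It called 34.6% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 92.4% of those changed 4-fold. Of its 730 calls, 64 (8.77%) were unchanged genes, so the share of false calls in the simulation was above the nominal level. The simulation changed few genes and gave both groups the same dispersion, unlike the data. These rates therefore need not hold for the real comparison. Counts simulated with the observed length trend alone, set equal at all abundances, gave 0 calls with edgeR, with and without the length correction. In these counts 1934 genes without the correction and 709 with it had an unadjusted p under 0.05. The observed trend was stronger in abundant genes, so the 0 calls do not show how many it would give. With changed genes added to the simulated trend, 118 of 200 were recovered after the correction.

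Replicate libraries were compared before averaging. Chi-square per degree of freedom between pairs was 9.29 to 14.9 in normoxia and 33.8 to 98.2 in chronic hypoxia, far above sampling noise, so no library was treated as a repeat of another.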

Results

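RNA was sequenced from the hearts of 8 adult Sprague Dawley rats, an outbred laboratory strain, to compare cardiac gene expression under chronic hypoxia, a sustained exposure to reduced oxygen, with that under normoxia. Each group had 4 rats, with 1 library per rat. Total counts in normoxia libraries 1 to 4 were 31287841, 28199908, 28711209 and 29733831. Those in hypoxia libraries 1 to 4 were 29083620, 32160710, 26229304 and 31148137. The group means of these totals differed by less than the spread between animals (n = 4 each, exact permutation p = 0.914). At this depth and spread the median SE of a log2 fold change was 0.14.

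Chronic hypoxia was accompanied by many modest changes in the heart. Of 14214 genes tested, 4693 (33.0%) were called, with 2516 higher and 2177 lower in hypoxia (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median called gene rose 1.56-fold or fell 1.43-fold, and 3828 calls (81.6%) were under 2-fold. Changes of at least 2-fold numbered 535 upward and 330 downward, and those of at least 4-fold numbered 127 and 42. All 4 values of one group lay above all 4 of the other in 4881 genes (34.3%, against 2.86% by chance). The same held in 4177 (89.0%) of the called genes, which were selected on these same values, so that share is not separate support.

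The balance between rises and falls depended on how the libraries were scaled. Under TMM scaling 53.6% of calls were higher in hypoxia and the median log2 fold change of all tested genes was 0.01. Scaling by library totals alone shifted the log2 fold changes by a median of −0.17, and 1426 genes were then higher and 3870 lower, so that 26.9% of calls were higher. On the log2(FPKM + 1) scale, which also uses library totals and understates the change of low genes, limma called 1195 genes higher and 3704 lower. Of the genes called under TMM, 76.8% were called again in the same direction with library totals alone and 67.1% on the log2(FPKM + 1) scale, where 482 of them fell below the filter of a mean FPKM of 1. Directions given here are relative to the TMM scaling.

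**Figure D1:**
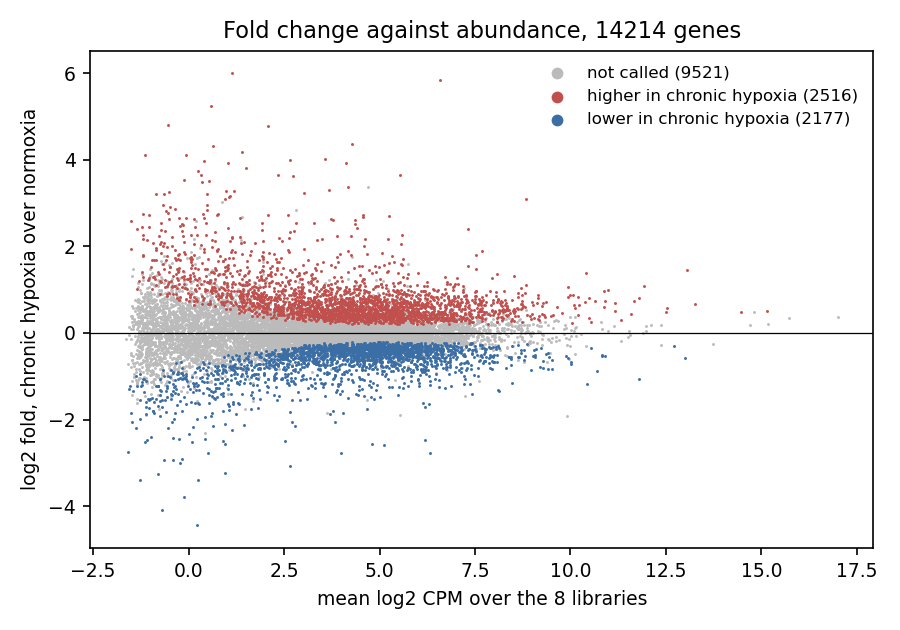
Log2 fold change of chronic hypoxia over normoxia (vertical axis) against mean log2 CPM over the 8 libraries (horizontal axis), with 1 point per tested gene. Red points are the 2516 genes called higher, blue points the 2177 called lower, and grey points the 9521 not called.

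Gene symbols were not used here because the files do not pair the Ensembl IDs with names, so genes are given by ID. These are the 2 largest changes in each direction among called genes with a mean of at least 1 CPM and groups that did not overlap. ENSRNOG00000006151, with a gene model of 781 bp, rose from 0.0647 ± 0.0470 CPM in normoxia to 4.36 ± 4.80 CPM in hypoxia (mean ± SD, n = 4 each), a log2 fold change of 5.99 (SE 0.99, edgeR adjusted p = 0.00214). ENSRNOG00000006579, of 773 bp, rose from 0.0721 ± 0.0620 to 2.89 ± 3.49 CPM, a log2 fold change of 5.24 (SE 1.04, edgeR adjusted p = 0.00488). Both rested on few counts in normoxia, 1 to 4 and 1 to 5 per library, against 29 to 295 and 12 to 209 in hypoxia. Hypoxia library 3 was highest for both, at 11.3 and 8.01 CPM, and without it the log2 fold changes were 4.91 and 3.97. Without normoxia library 3 that of ENSRNOG00000006579 was 5.96. All of these estimates stayed past the threshold.

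Among the genes that fell, ENSRNOG00000037364, of 255 bp, went from 2.05 ± 0.770 CPM in normoxia to 0.0922 ± 0.0796 CPM in hypoxia (mean ± SD, n = 4 each), a log2 fold change of −4.44 (SE 0.55, edgeR adjusted p = 6.09e-04). Its counts per library were 41 to 94 in normoxia and 0 to 5 in hypoxia. The count of 0 was in hypoxia library 2, where it allows up to 0.104 CPM. ENSRNOG00000046601, of 5563 bp, went from 2.02 ± 0.327 to 0.187 ± 0.135 CPM, with 57 to 76 counts per library in normoxia and 2 to 11 in hypoxia. Its log2 fold change was −3.39 (SE 0.39, edgeR adjusted p = 4.67e-04). Leaving out hypoxia library 3 moved the first to −5.02, and leaving out hypoxia library 2 moved the other to −4.02, both still past the threshold.

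The direction of change followed the length of the gene model. Genes called higher in hypoxia had a median length of 1610 bp, those called lower 3505 bp, and those not called 2361 bp. In the shortest of 10 equal length bins (49 to 889 bp), 484 genes were higher and 96 lower, with a median log2 fold change of 0.35 over the bin. In the longest (5214 to 29464 bp), 78 were higher and 528 lower, with a median of −0.23. With the length trend of each library removed, a correction chosen after seeing the data, 2060 genes were higher and 1718 lower, with 239 and 150 in the shortest bin and 198 and 189 in the longest. Across the 14214 genes, which are not independent replicates, Spearman's rho between log2 fold change and length was −0.303. Divided into 5 equal bins from low to high abundance, rho was 0.0112, −0.219, −0.377, −0.492 and −0.547, so the relation was close to 0 in the least abundant genes and strongest in the most abundant. Without the filter on low counts, which adds such genes, rho was −0.0809 over 21301 genes.

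**Figure D2:**
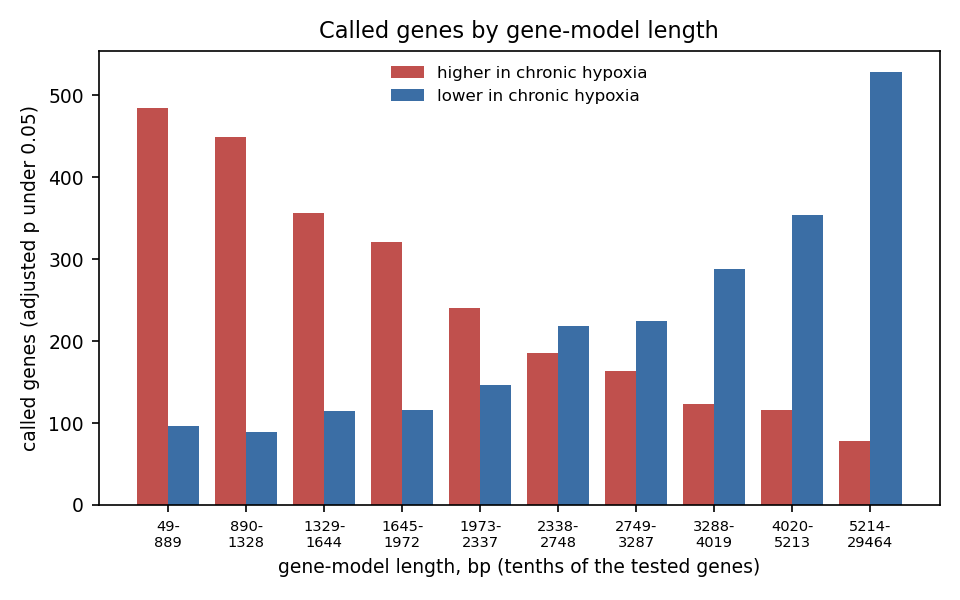
Number of called genes (vertical axis) in 10 equal bins of gene-model length in bp (horizontal axis), with genes higher in chronic hypoxia in red and lower in blue. The bars for higher genes go from 484 in the shortest bin to 78 in the longest, and those for lower genes from 96 to 528.

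Taken library by library against the mean of all 8, the relation with length separated the groups, in measures chosen after it was seen. The deviation of log2 CPM from the mean of the 8 libraries correlated with length across genes at a rho of 0.229, 0.295, 0.232 and 0.224 in normoxia libraries 1 to 4, and at −0.357, −0.239, −0.00460 and −0.205 in hypoxia libraries 1 to 4. As the mean is that of the same 8 libraries, opposite signs largely follow from the relation above, and these values are not separate support for it. The group means of 0.245 ± 0.0334 and −0.201 ± 0.147 (SD, n = 4 each) differed with an exact permutation p of 0.0286 (adjusted 0.0476), the smallest this design can give, which is reached when all 4 values of one group lie beyond all 4 of the other. The mean gene-model length per count was 2610 ± 15.8 bp in normoxia and 2281 ± 66.1 bp in hypoxia (n = 4 each, exact permutation p = 0.0286, adjusted 0.0476), shorter in 4 of 4 hypoxic hearts. Between single libraries, the rho of length with the difference in log2 CPM, normoxia minus hypoxia, was 0.122 to 0.363. Its lowest values were for hypoxia library 3, with 0.122, 0.130 and 0.123 against normoxia libraries 1, 3 and 4. Within groups it reached −0.141 for normoxia library 1 minus 2 and −0.265 for hypoxia library 1 minus 3. Some pairs within a group thus differed with length as much as some pairs between groups.

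Counts were concentrated in fewer genes in the hypoxic hearts. The 10 most abundant genes held 34.0 ± 0.826% of counts in normoxia and 38.9 ± 2.91% in hypoxia (SD, n = 4 each, exact permutation p = 0.0286, adjusted 0.0476). This share was chosen before the data were seen, but its adjusted p passes only because several measures chosen afterwards share the smallest possible p. The number of genes that together held 50% of counts was 82.5 ± 7.59 in normoxia and 45.8 ± 15.2 in hypoxia (n = 4 each, exact permutation p = 0.0286, adjusted 0.0476). The most abundant gene alone held 12.1 ± 0.432% and 13.8 ± 0.958%, which did not pass (n = 4 each, exact permutation p = 0.0571, adjusted 0.0816). As a share of summed FPKM, which weights short genes more, the 10 genes differed by 2.51 percentage points and the difference did not pass (exact permutation p = 0.229).

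Fewer genes had at least 1 count in hypoxia, by a margin that differed between the animals. At least 1 count was found for 18075 ± 44.8 genes in normoxia and 17722 ± 279 in hypoxia (SD, n = 4 each, exact permutation p = 0.0286, adjusted 0.0476). At an equal depth of 26229304 counts the numbers were 17929 ± 39.1 and 17589 ± 319, and the difference did not pass (n = 4 each, exact permutation p = 0.0857, adjusted 0.107). Hypoxia libraries 1 and 2 were then at 17378 and 17260 genes, below the normoxia range of 17903 to 17987, library 4 was at 17804, and library 3 was inside that range at 17914. With the 20 most abundant genes also left out, the numbers were 17818 ± 44.5 and 17573 ± 346 (n = 4 each, exact permutation p = 0.4, adjusted 0.444). Hypoxia libraries 1 and 2 stood at 17299 and 17251 genes there, library 4 at 17850 was inside the normoxia range of 17773 to 17875, and library 3 at 17894 was above it. The difference of −244 genes was −153 without hypoxia library 1 and −137 without hypoxia library 2.

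The hypoxic hearts differed more from one another than the normoxic ones did. Pearson's r of log2 CPM across genes was 0.987 to 0.991 between normoxia libraries, 0.966 to 0.983 between hypoxia libraries and 0.951 to 0.968 between libraries of different groups. The biological coefficient of variation from edgeR was 9.56% within normoxia and 22.9% within hypoxia. The median SD of a gene's log2 CPM was 0.13 in normoxia and 0.23 in hypoxia, and 78.7% of genes had the larger SD in hypoxia. The first principal component (49.0% of variance) separated the groups, with normoxia at −36.2 to −29.6 and hypoxia at 25.4 to 45.5. On the second (20.9%), hypoxia libraries 1 and 2 lay at −37.9 and −29.8 and libraries 3 and 4 at 29.3 and 27.9, while the normoxia libraries lay between −1.01 and 8.10.

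**Figure D3:**
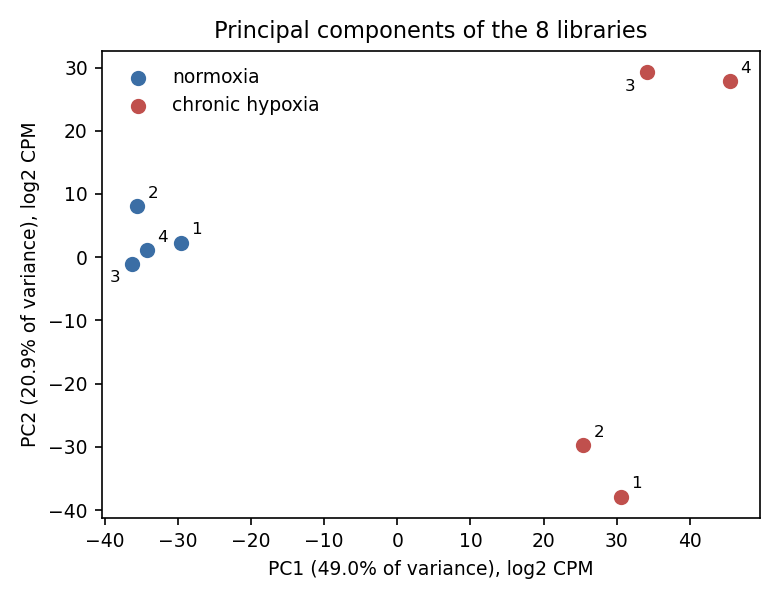
First and second principal components of log2 CPM, with 49.0% and 20.9% of the variance on the horizontal and vertical axes. Each point is 1 library with its replicate number, normoxia in blue and chronic hypoxia in red, and the hypoxia libraries are spread from −37.9 to 29.3 on the second component.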

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

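The tests of the length relation in this part, the rho of each library included, were chosen only after the relation was seen.

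Normoxia library 2 stood apart from the other normoxia libraries in how its expression followed gene-model length, with a rho of 0.295 against 0.224 to 0.232. It was the 1 library that stood apart among 28 groups of 4 tested. Chance alone marks about 5% of groups, so 1 in 28 is no more than chance would give. It lay farther from the hypoxia libraries than the other normoxia libraries did, and without it the difference between the group means of rho was −0.430 in place of −0.447.

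Longer gene models were lower and shorter ones higher in chronic hypoxia. A few very abundant genes do not account for this, since rho was −0.377 in the middle of 5 abundance bins, nor do gene models that lack untranslated regions, since rho was −0.336 in models of a length not divisible by 3. Those of a length divisible by 3, a mixture of models with and without such regions, gave −0.265. RNA integrity or fragment size that differed between the groups may produce such a relation and cannot be told apart from the exposure itself, because every hypoxia library lay below every normoxia library, with a gap of 0.229 in rho, and no integrity values were used here. A response of the hypoxic heart that involves short and long genes differently also stays open and was not tested. GC content was not tested, as no genome sequence was used here.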

How the results depend on the processing

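The length correction, voom with 1 variance per group, the removal of 2 hypoxia libraries at once, and the per-library measures other than total counts and the share of the 10 most abundant genes were chosen only after the results were seen. The number of called genes stayed within 1.5 times of 4693 in all 26 alternatives, from 3315 to 5982. Leaving out each library gave 3315 to 4758 calls, 1809 to 2554 higher and 1506 to 2310 lower. The split by direction moved with the scaling: library totals alone gave 1426 higher and 3870 lower, log2(FPKM + 1) gave 1195 and 3704, log2(FPKM + 0.1) gave 1195 and 3688, and log2(FPKM + 1) without a filter gave 1108 and 3548. All 4 use library totals, which moved the median log2 fold change by −0.17 to −0.18. With the replicate number as a block 3841 genes were called, but the numbers did not pair the animals: same-number correlations were −0.0847 to 0.0187, and 0 of 4 normoxia libraries correlated best with their own number. A filter at a mean of 5 CPM left out all 4 printed genes, and a filter at a mean FPKM of 1 left out ENSRNOG00000046601. In the remaining 98 combinations of a gene and an alternative, the 4 genes kept their direction in 98 and their call in 97. Their log2 fold changes were much smaller on the unfiltered log2(FPKM + 1) scale, at 2.11 for ENSRNOG00000006151, 1.63 for ENSRNOG00000006579, −2.79 for ENSRNOG00000037364 and −0.43 for ENSRNOG00000046601, as the added 1 outweighs low values. ENSRNOG00000006579 had an adjusted p of 0.0722 in limma on that scale, where alternatives otherwise gave 1.57e-05 to 0.0319. With a library left out, no p was computed for the 10 per-library measures and only direction was read. It held in each left-out library for all but total counts, whose difference (exact permutation p = 0.914 over all 8) changed sign without normoxia library 2 or 3 or hypoxia library 2 or 4. The alternatives for gene lists and for mitochondrial transcripts were not run, for want of gene names. The filter on low counts kept 7335 genes out of the test, and thinning to the smallest total still gave 4601 calls.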

Other observations

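The tests of the length trend and of dominant genes as the whole cause of the calls, and those of the spread between hypoxia libraries were chosen only after those results were seen.

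Some genes were detected in every library of one group and in no library of the other. There were 27 with counts in all 4 normoxia libraries and 0 in all 4 hypoxia libraries, and 16 of the reverse kind. All were of low abundance, with at most 20 and 31 counts summed over the group that had them.

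Calls were more frequent among abundant genes, from 16.5% of the least abundant of 10 abundance bins to 48.6% of the most abundant. In the most abundant bin 419 genes were higher and 272 lower in hypoxia. A change of a given size is easier to detect at high counts, and the rate of calls per bin was not corrected for that.

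In 516 called genes the groups overlapped. The one with the largest change among those of at least 1 CPM was looked at after its values were seen, and its ID is not printed. It stood at 245 and 505 CPM in hypoxia libraries 3 and 4, at 2.60 and 2.39 CPM in hypoxia libraries 1 and 2, and at 1.57 to 5.77 CPM in the normoxia libraries. Its log2 fold change of 5.84 (SE 1.56, edgeR adjusted p = 0.0178) therefore came from 2 of the 4 hypoxic animals.

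The number of called genes was set against technical explanations. Of the 35 splits of the 8 libraries, 1, the real one, gave as many calls, with 4693 against at most 1 in the others. That is the smallest share that 35 splits can give, so chance is argued against but not excluded. The other splits mix the groups, which puts the group difference into the spread within each side, so few calls there decide little. A technical difference between whole groups would leave the same result. Library size is argued against by the 95.5% of calls made again once all libraries were thinned to one total. The 99.5% made again without the 20 most abundant genes decides nothing, as TMM scaling hardly responds to them. With library totals alone 76.8% were made again, but library totals keep the effect of dominant genes that TMM removes. That share therefore cannot decide whether dominant genes are the whole cause. The balance of rises and falls under library totals turned to 26.9% higher and stays open. Gene-model length is tied to the calls, with a rho of −0.389 over the called genes. Once 1 trend per library was removed, 67.8% were made again in the same direction. That trend was fitted over all abundances, while the relation with length was stronger in abundant genes, so part of it may remain there. The 67.8% therefore cannot decide whether length is the whole cause. The exposure may account for calls that length does not, a hypothesis that shares of atrial tissue or blood in the samples leave open, as these need gene names and were not tested.

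The hypoxia libraries spread more widely than the normoxia libraries, with a ratio of median SDs of 1.85. Library size does not account for it (ratio 1.82 after thinning), nor does a single hypoxia library (at least 1.66 whichever was left out). A length trend common to all abundances does not either (1.80 once removed), but a trend that differs with abundance was not removed and stays open. Among the 3 ways of parting the 4 hypoxia libraries in pairs, 268 genes lay at least 2-fold apart between libraries 1 and 2 and libraries 3 and 4, against 40 and 29 for the others and 9 to 25 in normoxia. A difference between hypoxic animals in their response, and a difference in how pairs of these hearts were sampled or processed, both may underlie this, and no label used here separates them.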
